A study of Spirodela polyrhiza with 12 samples.

How the data were processed

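RNA was measured by sequencing in leaf samples of Spirodela polyrhiza, the giant duckweed, a small floating aquatic plant. Per the labels, 12 libraries fall into 3 groups of 4, kept at indoor, middle or high temperature, and the indoor group served as the control. The temperatures in degrees and the exposure times are not given in the sources used here. Per the labels' protocols, messenger RNA was selected by its poly(A) tail, the second cDNA strand was marked with dUTP and removed, adapters carried unique molecular identifiers, and libraries were sequenced as read pairs on an Illumina NovaSeq instrument.

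The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, without their roles or order. The genome build and annotation, and whether counting used the strand, are not given in the sources used here. Overlapping genes and near-identical gene copies are therefore uncertain, since the counting may have divided reads between them. The deposited table holds 18099 genes by identifier, and per the file headers each library has an FPKM column (fragments scaled to transcript length and library size) and a count column. Within each gene the deposited counts were proportional to the deposited FPKM after rounding up to a whole number: all 18099 genes fitted this within a tolerance of 0.05%, against 10773 for rounding to the nearest whole number. The deposited counts are thus estimated counts that were already whole, and they were used as deposited. The commonest count above 0 was 4, found 1807 times, against 470 times for a count of 1, so a sequenced fragment may add several counts, which was not tested further. On that reading a count of 0 was given a floor of 12 counts per library, which is 3 fragments of 4 counts. This floor covers counting error only. The files do not pair identifiers with gene names, and no reference annotation was used here. The aquaporin family named in the series title and the gene lists fixed beforehand were therefore not analysed here.

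The total estimated count per library ran from 23655239 to 32711880. Genes with an FPKM of at least 1 in at least 4 libraries were tested, which kept 15209 genes and left out 2890. The design written before the data were examined used limma on log2(FPKM + 1) for a table of FPKM alone, and edgeR if it also held raw counts. Counts were present but estimated rather than raw, so that condition was not met as written. The test used was still edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, robust and trended prior, TMM scaling). TMM sets library factors so that most genes do not change. All 12 libraries entered a single fit with a term per group, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05, and a second count added a fold change of at least 2. The scaling that came with the choice of test mattered. Between high and indoor temperature limma, without TMM, called 1178 genes higher and 8772 lower, against 2596 and 2396 with edgeR and TMM. With library totals in place of TMM, edgeR called 1170 and 8699. After quantile normalization, which gives all libraries the same distribution of values, limma called 2470 and 2828. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The common biological coefficient of variation was 30.1%. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

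The test was checked on counts simulated from the means of the real libraries for 15209 genes. For high against indoor temperature, 44% of 50 genes changed 2-fold and 88% of 50 genes changed 4-fold were recovered, with 7 unchanged genes called. For middle against indoor temperature the recovered shares were 36% and 90%, with 6 unchanged genes called. For high against middle temperature they were 38% and 78%, with 8 unchanged genes called. Of 50 genes changed 1.5-fold, 2%, 8% and 4% were recovered in these comparisons in turn. With so few genes changed, changes of 2-fold or less were thus mostly missed in the simulated data. The real comparisons called far more genes, which loosens the adjusted threshold, so these shares do not carry over to them. Between high and indoor temperature, 2737 of the 4992 called genes changed at least 2-fold, and the rest changed less.

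Genes are named by a rule written before the data were examined. For each comparison, with no gene names to draw on, it takes the 2 genes with the largest rise and the 2 with the largest fall in mean log2(FPKM + 1). These had to be called, reach a mean FPKM of at least 5 in the higher group, and have no overlap between the libraries of the groups. Library measures were compared by two-sided exact permutation tests in scipy 1.17.1. No pair of replicates had identical counts, and the chi-square per degree of freedom between replicates, over genes with a summed count of at least 20, ran from 50.2 to 186, so no library was counted as a duplicate. For the overlap of responses, 20 sets of counts with no effect were simulated for all 3 groups, controls included, from the indoor means and the fitted dispersions. Alternatives comprised other pseudocounts, filters, scalings, priors and weights, a replicate term, fits of 2 groups alone and the omission of each library. DESeq2 1.42.0, scaling by library totals and counts divided by 4 were added after the data were seen. limma 3.58.1 on log2(FPKM + 1), the test written beforehand for FPKM alone, was run as an alternative. Figures were drawn with matplotlib 3.10.9.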

Results

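Transcript abundance was measured in leaf samples of Spirodela polyrhiza, a floating duckweed, kept at indoor, middle or high temperature, with 4 libraries in each group. The series title places the comparisons in the context of high-temperature stress. The total estimated count per library was 23655239 to 28826999 at indoor temperature, 24942682 to 32467069 at middle temperature and 25575920 to 32711880 at high temperature. A difference in total between the high and indoor groups was not detected (two-sided exact permutation test, p = 0.2, n = 4 per group). Genes are given by identifier, because the files do not pair identifiers with gene names.

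High-temperature libraries were dominated by few transcripts. The 10 most abundant genes of each library held 17.6% ± 1.87 of the counts at high temperature, 4.99% ± 0.36 at indoor temperature and 4.26% ± 0.38 at middle temperature (SD, n = 4). The most abundant genes that together held 50% of the counts numbered 235.75 ± 62.9 at high temperature and 930.5 ± 62.2 at indoor temperature. Both measures separated all 4 high from all 4 indoor libraries (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 libraries can give, and 0.0545 after Benjamini-Hochberg adjustment over 21 comparisons, which misses the threshold). The genes that led the high-temperature libraries were not those that led the controls. The 10 genes with the highest mean share at high temperature held 17.5% ± 1.92 of the counts there, 1.62% ± 0.54 at middle temperature and 0.378% ± 0.11 at indoor temperature. None of the 10 was among the indoor group's 10 most abundant genes, whereas 6 genes were shared between the indoor and middle sets. These 10 were chosen for their share at high temperature, so their rise over indoor temperature is no independent test. They were higher by log2 fold changes from 3.98 to 8.13, and 8 of the 10 were also called higher at middle than at indoor temperature by edgeR's quasi-likelihood test. Of the indoor group's 10 most abundant genes, 1 was called higher and 0 lower at high temperature, with a median log2 fold change of 0.03 and the lowest at -1.23. These fold changes are TMM-scaled. As a share of the counts the same genes fell from 4.70% ± 0.29 at indoor to 3.01% ± 0.39 at high temperature.

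**Figure D1:**
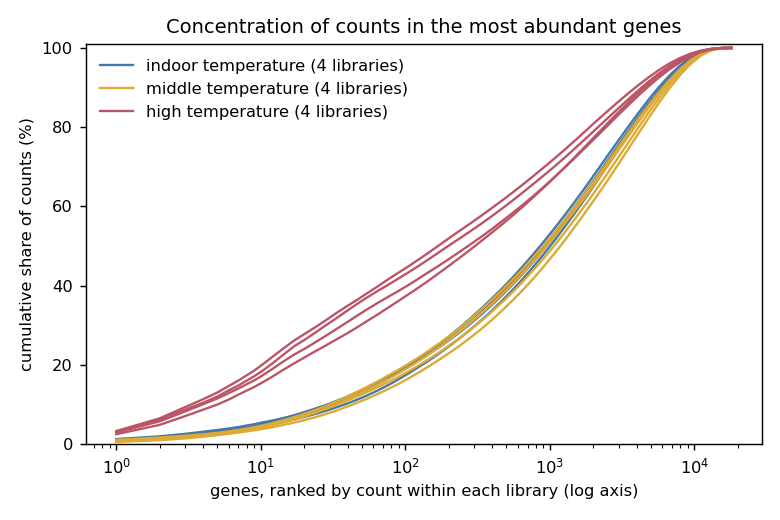
Cumulative share of the estimated counts (%) against the number of genes ranked by count within each library, on a log axis, with a line per library. The 4 high-temperature lines rise earliest, the 10 most abundant genes holding 17.6% of the counts on average, against 4.99% at indoor temperature.

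The libraries separated by group. Over TMM-scaled log2 relative counts, the first principal component held 43.3% of the variance and ordered the groups from indoor through middle to high temperature. The second held 23.4% and set the middle group apart from both others. On deposited log2(FPKM + 1), without TMM, the first component held 50.1% and the middle libraries overlapped the indoor ones along it. Spearman correlations over genes, which are not independent replicates, were 0.959 to 0.981 within groups and 0.912 to 0.929 between high and indoor libraries. They were 0.924 to 0.941 between middle and indoor libraries and 0.929 to 0.961 between high and middle libraries, the last overlapping the range within groups.

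**Figure D2:**
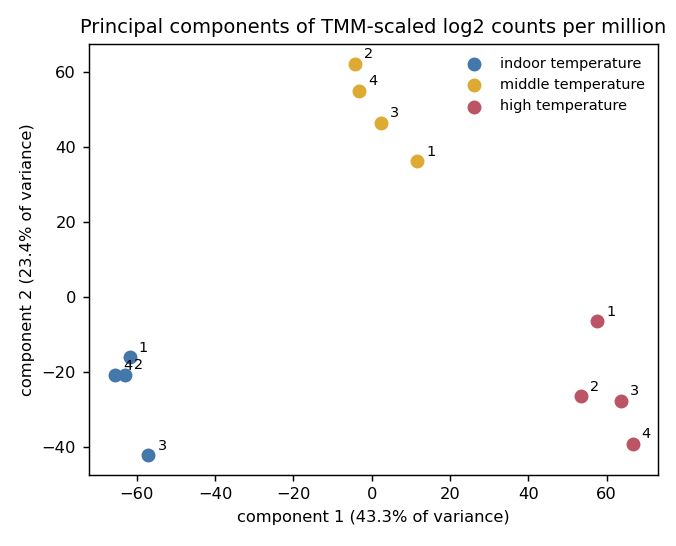
First and second principal components of TMM-scaled log2 counts relative to the library total, with a point per library, numbered by replicate and coloured by group. The 12 libraries form 3 separate groups along components holding 43.3% and 23.4% of the variance.

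The comparison of high with indoor temperature addressed the response to high-temperature stress. By the naming rule, the largest rise in mean log2(FPKM + 1) was that of Spipo10G0024000.v2, from an FPKM of 8.63 ± 2.43 at indoor temperature through 143 ± 77.5 at middle to 4767 ± 1212 at high temperature (SD, n = 4). Its log2 fold change between high and indoor temperature was 9.79 ± 0.55 (SE). Spipo10G0041600.v2 rose from 3.67 ± 0.81 to 1775 ± 312, a log2 fold change of 9.59 ± 0.61. Spipo28G0015100.v2 fell from 62.9 ± 14.6 to 0.75 ± 0.44, a log2 fold change of -5.68 ± 0.38, and Spipo8G0061200.v2 fell from 142 ± 67.1 to 6.64 ± 4.92, a log2 fold change of -3.79 ± 0.55. The Benjamini-Hochberg adjusted p-values of edgeR's quasi-likelihood test were 3.95e-08, 1.35e-07, 1.21e-07 and 0.000222 for these genes in turn.

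Of 15209 genes tested between high and indoor temperature, 4992 were called, 2596 higher and 2396 lower at high temperature. With TMM scaling 698 genes were at least 4-fold higher and 227 at least 4-fold lower, and 179 against 22 genes changed at least 16-fold in the fitted values. In the group with the lower level, 16 of the 179 and 8 of the 22 had a count of 0 in every library, where the fitted fold is no bound. Of the 179 genes at least 16-fold higher, 146 were also called higher and 0 lower at middle temperature, and 157 were called higher at high than at middle temperature. Of the 22 genes at least 16-fold lower, only 6 were also called lower and 1 was called higher at middle temperature. Both comparisons share libraries with the one that chose these genes, so these counts are no independent test. The mean FPKM of the 179 genes had medians of 1.93 at indoor, 17.5 at middle and 60.4 at high temperature. The libraries of the groups did not overlap in TMM-scaled counts for 30.4% of the genes tested and in deposited FPKM for 53.6%, against 2.86% by chance. The split into higher and lower depended on the scaling. With library totals in place of TMM, which moved the median log2 fold change of all genes from -0.04 to -0.73, 1170 genes were higher and 8699 lower. Of these, 407 were at least 4-fold higher and 783 at least 4-fold lower, so the balance of changes of at least 4-fold turned with the scaling. At 16-fold or more, 120 genes were higher and 49 lower with library totals.

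Middle temperature was compared with indoor temperature to measure the response to the intermediate treatment. Spipo16G0039200.v2 rose from an FPKM of 5.05 ± 2.34 to 200 ± 73.8, and reached 1420 ± 286 at high temperature (SD, n = 4). Spipo8G0028900.v2 rose from 0.82 ± 0.25 to 50.4 ± 16.4 and stood at 47.8 ± 13.5 at high temperature. Their log2 fold changes between middle and indoor temperature were 5.18 ± 0.43 and 5.80 ± 0.30 (SE). FPKM values are as deposited, without the TMM scaling used for the log2 fold changes. The mean TMM factor was 1.25 at middle and 0.707 at high temperature, so like FPKM values in these groups are not like TMM-scaled values. Spipo21G0028100.v2 fell from 650 ± 379 to 64.1 ± 22.5, a log2 fold change of -3.44 ± 0.56, and Spipo0G0103400.v2 fell from 244 ± 125 to 28.9 ± 21.8, a log2 fold change of -3.16 ± 0.87. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p-values were 5.62e-06, 3.29e-07, 0.000575 and 0.0156 in that order.

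Between middle and indoor temperature 5614 genes were called, 2927 higher and 2687 lower at middle temperature, of which 1626 and 1074 changed at least 2-fold. Fitted changes of at least 16-fold were found for 33 higher and 3 lower genes, of which 12 and 1 had a count of 0 in every library of the group with the lower level. The groups did not overlap in TMM-scaled counts for 38.0% of the genes and in deposited FPKM for 36.5%, against 2.86% by chance. With library totals in place of TMM the median log2 fold change of all genes moved from -0.02 to 0.12, and 3385 genes were called higher and 1813 lower, of which 1949 and 777 changed at least 2-fold.

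High and middle temperature were compared directly to test the difference between the treatments. Spipo4G0115200.v2 rose from an FPKM of 3.76 ± 0.73 at middle to 286 ± 74.4 at high temperature, and Spipo20G0008500.v2 from 71.2 ± 32.7 to 3882 ± 562 (SD, n = 4). Their log2 fold changes were 7.06 ± 0.28 and 6.56 ± 0.48 (SE), with Benjamini-Hochberg adjusted p-values of 5.56e-09 and 1.71e-06 in edgeR's quasi-likelihood test. Spipo0G0104700.v2 had an FPKM of 12.4 ± 0.92 at indoor and 30.5 ± 0.88 at middle temperature and a count of 0 in all 4 high-temperature libraries. Against the floor of 12 counts per library it was at least 68.7-fold lower at high than at middle temperature (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.74e-09). Spipo15G0048000.v2 was at 35.6 ± 8.39 at middle and 1.87 ± 2.88 at high temperature, with a log2 fold change of -3.50 ± 1.11 and an adjusted p of 0.0355 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This call was near the threshold. It was lost in 7 of the 12 fits that left out a library (edgeR, highest Benjamini-Hochberg adjusted p = 0.0818). The log2 fold change kept its direction in all of these fits, which the lack of overlap asked for by the naming rule made nearly certain. It ran from -5.52 without high replicate 1 to -3.10 without high replicate 4. Whether the loss came from fewer libraries or from particular ones was not tested.

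Between high and middle temperature 4616 genes were called, 2417 higher and 2199 lower at high temperature, of which 1008 and 1016 changed at least 2-fold. Fitted changes of at least 4-fold were found for 279 higher and 148 lower genes, of which 2 and 8 had a count of 0 in every library of the group with the lower level. The libraries of the groups did not overlap in TMM-scaled counts for 31.3% of the genes and in deposited FPKM for 58.0%, against 2.86% by chance. With library totals, which moved the median log2 fold change of all genes from 0.0033 to -0.82, 505 genes were higher and 9562 lower, of which 129 and 927 changed at least 4-fold.

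**Figure D3:**
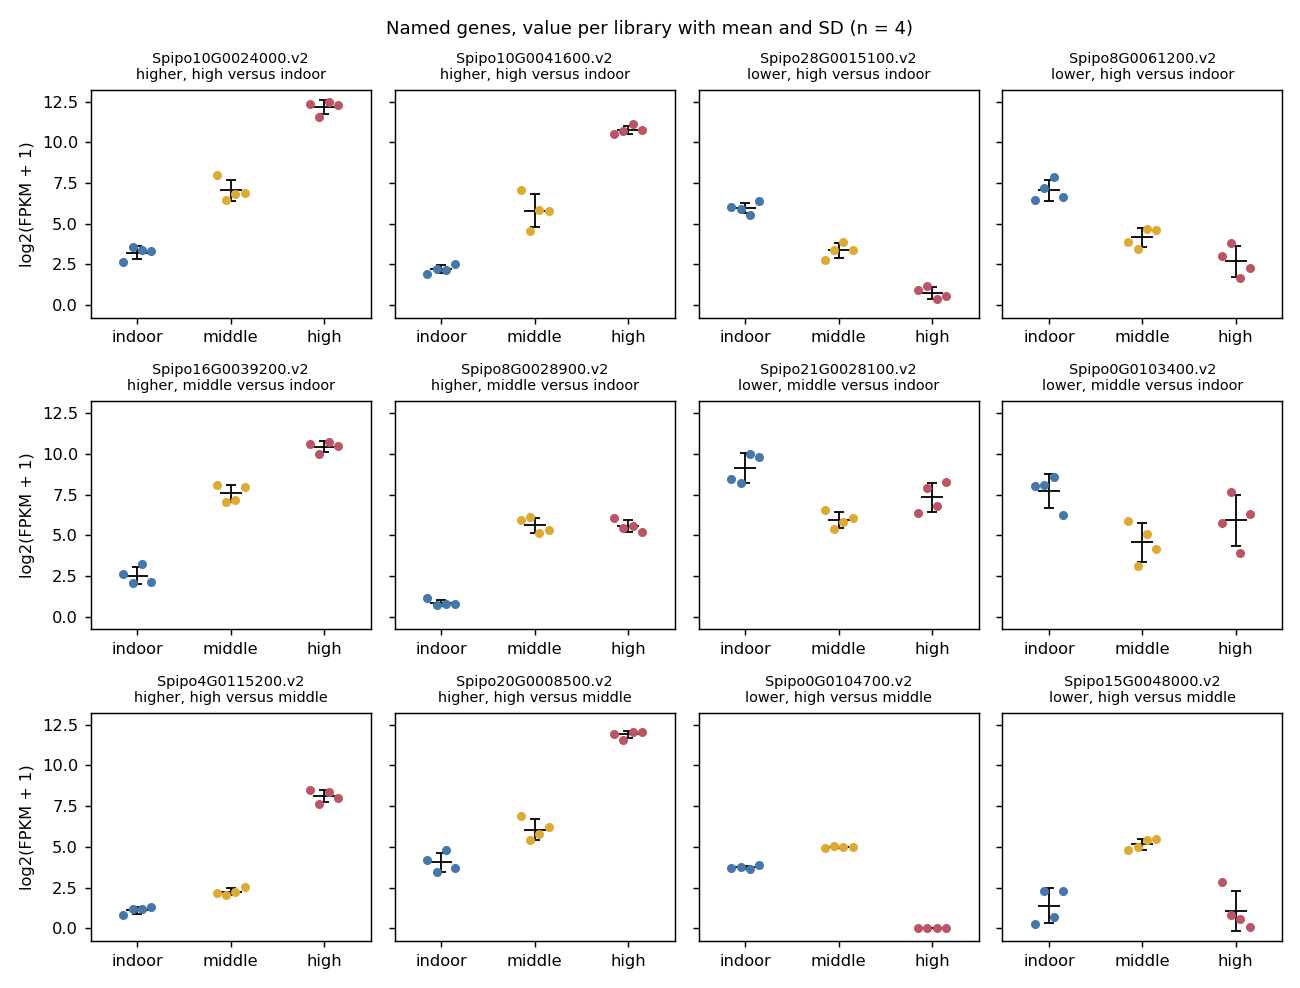
Expression of the 12 named genes as log2(FPKM + 1) in each library (points), with the group mean and SD (n = 4), a panel per gene. Spipo10G0024000.v2 climbs over both steps of temperature, and Spipo0G0104700.v2 is at 0 in all 4 high-temperature libraries. Spipo8G0028900.v2 is similar in the middle and high groups on this scale, which has no TMM scaling.

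Over the 3 groups, 7995 genes differed. A total of 442 genes rose at both steps of temperature and 98 fell at both. Another 885 genes were higher at middle than at indoor temperature and lower again at high temperature, and 970 showed the opposite course. These courses depended on the scaling: with library totals 2541 genes peaked at middle temperature, 94 had their lowest level there, 247 rose at both steps and 618 fell at both.

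The responses to middle and high temperature were compared over the same controls. Among genes called in both comparisons with the controls, 1612 were higher in both, 1081 were lower in both and 83 changed in opposite directions. Independent lists of these sizes would share 500 higher and 423 lower genes. In 20 simulations with no effect, hardly any gene was called in either comparison, so they give no overlap to set beside these counts. With the 4 control libraries split into 2 and 2, so that the comparisons shared none, 966 to 1146 genes were higher in both and 508 to 656 lower in both over 6 splits. Independent lists of the sizes in those splits would share 228 to 373 higher and 157 to 305 lower genes. A deviation common to all 4 indoor libraries would still enter both comparisons, and the splits cannot remove it. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.659 and Spearman's rho 0.601, against means of 0.491 and 0.465 in the simulations, where the shared controls alone correlate the comparisons. With split controls Pearson's r was 0.443 to 0.600. The covariance was 0.722 against 0.0673 in the simulations, a difference of 0.655, and it was 0.591 to 0.717 with split controls. These overlaps and correlations rest on TMM scaling. With library totals 1170 genes in all were higher at high than at indoor temperature, fewer than the 1612 above, and 8699 were lower. At middle temperature 3385 were then higher and 1813 lower. How the shared genes split into higher, lower and opposite with library totals was not counted here.

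**Figure D4:**
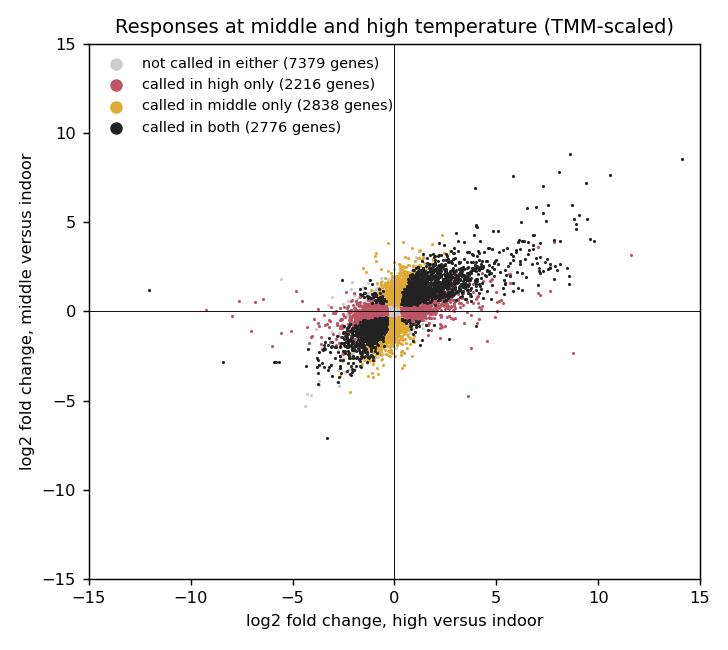
Log2 fold change at middle temperature against that at high temperature, both relative to indoor temperature and TMM-scaled, with a point per gene tested. Points are coloured by the comparison in which the gene was called, 2776 genes in both, and changes beyond 10 in size belong to genes with a count of 0 in every library of a group, where the fitted change is no bound.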

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

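The tests behind this part were fixed before the data were examined. Among 54 sets of 4 libraries, 2 held a library whose gap to the nearest of the others took up more of the range than Dixon's 95% critical value, and chance alone marks about 1 in 20 sets. The FPKM of Spipo10G0024000.v2 in middle replicate 1 was 258, against 87.9 to 116 in the other middle-temperature libraries, a gap of 0.833 of the range. The FPKM of Spipo15G0048000.v2 in high replicate 1 was 6.17, against 0.048 to 0.749 in the other high-temperature libraries, a gap of 0.886 of the range. Without high replicate 1 the log2 fold change of Spipo15G0048000.v2 between high and middle temperature moved from -3.50 to -5.52.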

How the results depend on the processing

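limma on log2(FPKM + 1) was the test written beforehand for a table of FPKM alone. DESeq2, scaling by library totals alone and counts divided by 4 were chosen after seeing the data, and the other alternatives before. Over 27 alternatives, 316 of 324 values of named genes kept their direction and their side of the threshold and 0 reversed. The other 8 were all Spipo15G0048000.v2 between high and middle temperature, which kept its direction at an adjusted p (edgeR, Benjamini-Hochberg) above the threshold. Of 377 summary counts, 321 stayed within 1.5 times the reported count, and the 56 beyond it all lay in settings without a correction for the few genes that take many counts. The settings with other pseudocounts, TPM and array weights used limma on log2 values. Scaling by library totals alone differs from the reported fit only in that correction.

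Between high and indoor temperature, where 4992 genes were called (2596 higher, 2396 lower, 2737 at least 2-fold), the called, higher, lower and at least 2-fold changed genes numbered 10019, 1198, 8821 and 5665 with a pseudocount of 0.1, and 9968, 1185, 8783 and 5713 with a pseudocount of 0.01. They numbered 9819, 1191, 8628 and 4587 on TPM, 9684, 1136, 8548 and 4476 with array weights, 9950, 1178, 8772 and 4487 with limma on log2(FPKM + 1), and 9869, 1170, 8699 and 5600 with library totals.

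Between high and middle temperature, where 4616 genes were called (2417 higher, 2199 lower, 2024 at least 2-fold), the same counts were 10262, 513, 9749 and 5974 with a pseudocount of 0.1, and 10153, 493, 9660 and 5952 with a pseudocount of 0.01. They were 10433, 525, 9908 and 5074 on TPM, 10311, 535, 9776 and 4573 with array weights, 10331, 536, 9795 and 4748 with limma on log2(FPKM + 1), and 10067, 505, 9562 and 5868 with library totals. Genes lower at middle than at indoor temperature, 2687 as reported, numbered 1788 with a pseudocount of 0.01 and 1787 on TPM. Genes differing among the 3 groups, 7995 as reported, numbered 12491 and 12365 with pseudocounts of 0.1 and 0.01, 12563 on TPM, 12479 with array weights, 12579 with limma on log2(FPKM + 1) and 12234 with library totals. After quantile normalization limma called 2470 genes higher and 2828 lower between high and indoor temperature, and 1946 and 2196 between high and middle temperature. Beyond the settings with library totals and quantile normalization, the cause was not tested.

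Leaving out each library in turn gave 4316 to 4873 called genes between high and indoor temperature, 4674 to 5871 between middle and indoor, 3275 to 4743 between high and middle, and 6884 to 7975 differing among the 3 groups. DESeq2 called 5705, 6286 and 5393 genes in the 3 comparisons. With the replicate number as a block, edgeR called 4572, 5072 and 3957 genes, and Spipo15G0048000.v2 had a Benjamini-Hochberg adjusted p of 0.0541, within a range up to 0.0818 over the alternatives that lost the call. The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.289 to 0.275, above 0.1 in 3 of 12 pairs, and the own number correlated best in 2 of 12. The alternatives listed beforehand for aquaporins and gene lists, including other set tests, were not run, because the files do not pair identifiers with gene names. At 4 libraries per group, changes of 2-fold or less were mostly missed in simulated data. Few genes were changed there, so this does not carry over to the real comparisons.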

Other observations

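The tests of the most abundant genes taking counts from the rest, of reads running into the next gene, and of total count by the group with a like excess or by pairs with the opposite difference, were chosen only after the result was seen.

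Genes with consecutive identifiers changed together more often than in any of 1000 permuted orders in 5 of the 6 sets of called genes examined. Identifiers of this plant carry a number before the letter G and a running number after it, used here only as an order. Between high and indoor temperature, genes called at least 2-fold higher formed 77 runs of 3 or more consecutive tested identifiers, holding 269 genes, the longest with 8, against a mean of 17.2 runs and a highest of 31 over 1000 permuted orders. Genes at least 2-fold lower formed 33 runs, against a mean of 5.9. Between middle and indoor temperature the higher and lower genes formed 45 and 29 runs, against permuted highest numbers of 28 and 14. Between high and middle temperature, higher genes formed 49 runs, the longest with 9 genes, against a mean of 4.6. The 12 runs of lower genes lay above the permuted mean of 4.5 but below the permuted highest of 17, which leaves this set undecided. Over 198 Fisher's exact tests of the number before the G, genes at least 2-fold higher at high than at middle temperature made up 45 of 377 genes under number 10 (11.9%, against 6.49% elsewhere, Benjamini-Hochberg adjusted p = 0.0261). In all, 8 of the 198 tests had an adjusted p under 0.05, 6 with a higher share than elsewhere and 2 with a lower one. Those with a lower share were numbers 15 and 19 among genes at least 2-fold higher at high than at indoor temperature, at 5.82% and 5.28%, against 10.7% elsewhere. Neighbouring genes are not independent, so these p-values are too small.

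The rank correlation of log2 fold changes of neighbours was 0.189 between high and indoor temperature, and up to 0.033 in permuted orders (p = 0.001, the smallest 1000 permutations can give). Reads of a gene running into the next would link direct neighbours, and genes 2 places apart correlated at 0.0749, above the permuted highest of 0.029. Permuted orders hold no link between neighbours at all, and a chain through the gene between could also exceed them, so this does not decide. Reads shared between near-identical tandem copies would need like lengths, yet neighbours differing over 2-fold in length correlated at 0.170, above the permuted highest of 0.044. This argues against shared reads of such copies as the whole cause, and truncated copies and reads running into the next gene stay open. A shared response of neighbouring genes to temperature may contribute and was not tested.

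On the deposited FPKM scale most genes were lower at high than at indoor temperature: the median change in log2(FPKM + 1) was -0.631. With all libraries rescaled to the same FPKM sum it was -0.62, and 82.1% of the genes tested were lower. Thinning to the smallest total left -0.632, but FPKM is already scaled to library size, so thinning could hardly move the median and decides nothing. A difference in total count is argued against by the 3 library pairs with the smaller total at high temperature, at -0.615 to -0.512. It is argued against by the middle-temperature libraries too: their totals exceeded the indoor ones by as much, yet their median change was 0.109, with library pairs from -0.053 to 0.320. Leaving out the 100 or 500 most abundant genes of the high-temperature libraries and rescaling gave -0.161 and -0.067. Library pairs ran from -0.306 to 0.013 and from -0.159 to 0.065. Removing genes chosen this way must raise the median, so this does not measure how far abundant transcripts took counts from the rest. The 10 genes with the highest mean share at high temperature held 17.5% of the counts there and 0.378% at indoor temperature. The share left for the rest was thus smaller at high temperature. How much of the median change this makes stays open. So do a true fall of most transcripts, as total RNA per cell was not analysed here, and the temperature itself.

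Between middle and indoor temperature the change depended on abundance: median log2 fold changes over 5 equal classes of genes from low to high abundance were 0.28, 0.12, 0.01, -0.12 and -0.21. The lowest minus the highest class was 0.491, and 0.484 after thinning all libraries to the same total. The fold changes are already scaled to library size, so thinning could hardly move this difference and decides nothing on depth. The difference was 0.400 to 0.547 without any single library and above 0 in 16 of 16 library pairs. In the 2 pairs with the smaller total at middle temperature it was 0.299 and 0.504, which argues against depth for those pairs. Between high and indoor temperature, with a like excess in total count, it was -0.12, with library pairs from -0.404 to 0.394, which adds nothing on depth. An even background over all genes may contribute. Library medians of FPKM over genes below the filter averaged 0.017 ± 0.034 at indoor and 0.096 ± 0.017 at middle temperature (SD). They averaged 0.132 at high temperature, where the trend was -0.12. A single indoor library had a median above 0 and supplied the whole indoor value. These FPKM values were TMM-scaled, unlike the deposited ones. The mean TMM factor was 1.25 at middle and 0.707 at high temperature, so the order of these groups need not hold as deposited. The excess at middle over indoor temperature was 0.243 of the FPKM gain of the lowest class. Over library pairs this excess was 0.00498 to 0.113 in FPKM, too scattered to decide. A response to temperature stays open.

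No other division of the same libraries that was tried gave as many called genes as the real one. Splits that mix the groups widen the spread within each side, which lowers their counts. The splits cannot tell temperature from another difference between the groups, as the libraries of a group may not be separate cultures. Of the 35 splits of the 8 libraries of a comparison into 4 and 4, 1 gave as many genes, the real split itself, in each comparison. A share of 1 in 35 is the smallest that these splits can give. The real counts were 4992, 5614 and 4616, and the highest of the other splits were 1, 1 and 0 genes. For the 3 groups, 1 of 100 splits gave as many as 7995 genes, the real one, and the highest other gave 2360.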
